A study of Mus musculus with 18 samples.

How the data were processed

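RNA-seq libraries of sorted immature B cells from mouse bone marrow were analysed from 1 table of gene counts covering all 18 libraries. Per the labels' protocols, marrow was released by crushing hind limb, hip and spine bones. Cells that were CD19+, B220 low, CD93+, IgM+ and CD24 high were sorted. Per the labels, the 6 adult mice were males kept on doxycycline food for 2 weeks, and their marrow had red cells lysed and Ter119, Gr1, CD11b and CD3e positive cells depleted on magnetic beads before the sort. The 12 neonates were 3 days old, their sex was not determined and their marrow had neither step. Full-length complementary DNA was made with a SMART-Seq v4 low-input kit and indexed with Nextera XT, which does not mark strand, and was sequenced on an Illumina NextSeq.

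The deposited values were RSEM expected counts per gene, made by the authors from reads aligned with STAR 2.7.1, per the labels' protocols. RSEM splits reads that match several genes by estimated probability. The labels' protocol text gives RSEM version 1.28 and the submitters' processing notes give 1.2.28. The notes also name DESeq2, Picard and the builds mm10 and NCBIM37 with no role, so the build behind the counts is not given in the sources used here. The deposited counts were already whole numbers (0 non-integer values were found), were not normalized and were not pooled over replicates. The table had 52550 lines with 52459 distinct symbols. Lines sharing a symbol (181) were kept apart, and 23467 lines were 0 in every library. Of the distinct symbols, 91.7% were present in the GENCODE M21 annotation of GRCm38, which was used for the position of Lin28b. Near-identical genes (Bcl2a1b and Bcl2a1d, H2-Q6 and H2-Q7, haemoglobins, histones, ribosomal protein genes with many processed copies, lambda light chain genes) share reads, so their separate values are uncertain, and so are those of genes overlapping a partner on the opposite strand.

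Groups came from the labels: adult mice with a tet-driven Lin28b transgene (n = 3), adult wild type mice (n = 3), and neonates with no (KO, n = 4), 1 (HET, n = 4) or 2 (WT, n = 4) functional Lin28b alleles. Both adult groups carry the same strain label, written for the tetO-LIN28B and rtTA lines. All neonates carry the label of a B6 Lin28b allele. Nothing in the labels says that replicates came from separate animals beyond being separate samples, so p-values measure the spread between these samples. No pair of libraries of the same group agreed within sampling noise. Age coincided with strain, doxycycline food and marrow preparation, so these cannot be told apart from age. Sex, read from sex-linked genes, was male in all adult WT libraries and in neonatal WT libraries 1 to 3. Without neonatal WT library 4, 1452 genes were called between the ages, 1404 of them among the 2031.

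Library totals ranged from 6.38 to 37.3 M counts: 27.8 to 37.3 M in adult transgenic, 27.4 to 37.2 M in adult WT, 9.91 to 27.0 M in neonatal KO, 6.38 to 23.4 M in neonatal HET and 12.8 to 25.1 M in neonatal WT libraries. A gene at 0 counts was given a floor of 3 counts, pooled over the group. Fold changes against a group at 0 in all its libraries were computed against that floor and are lower bounds. Floors and intervals cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules.

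Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its minimum count of 10, TMM factors, robust dispersion and quasi-likelihood F-tests, with Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. Standard errors (SE) of log2 fold changes were derived from the F statistic. The adult comparison used 6 libraries, the neonatal ones a single fit of 12, both comparisons between ages 7, and the difference between adult gain and neonatal loss 18. A slope per functional allele was fitted as the allele trend. CPM are counts per M counts of the library total.

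Gene lists were tested with camera in limma 3.58.1 on log-CPM (prior count 2), with a preset correlation of 0.01 and adjustment over the lists of a comparison. Only lists with at least 5 tested members entered. The p with an estimated correlation is given where it ends a call. The 28 lists covered let-7 microRNA targets, imprinted growth genes, B-1 cell genes, genes induced early by the B cell receptor (BCR), BCR signalling components, pro-B and pre-B genes, mature B genes, ribosomal proteins, ribosome biogenesis, translation factors, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, S phase, G2/M, interferon response, apoptosis regulators, early cell stress genes, lambda light chain and editing genes, sex-linked genes, and markers of erythroid cells, neutrophils, monocytes and macrophages, T and NK cells, megakaryocytes and platelets, plasma cells, plasmacytoid dendritic cells, and stroma and endothelium.

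The tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named 11 genes tied to Lin28b or early-life B cells, the 8 largest changes in each direction among called genes with mean CPM of at least 5 and no overlap between replicates, and up to 3 called members of each list with mean CPM of at least 1. Where fewer than 8 genes were taken that way, up to 5 genes per direction with the smallest unadjusted p were added and are said not to have passed. Genes outside the rule were added after their values were seen: Cd36, Slamf9 and Hck in the adult and age comparisons, Hba-a1 in the age comparison, Iglc2 and Map2 in KO against WT, Iglc2 and Pacsin1 in neonatal WT against adult transgenic cells, Slfn2, and the genes of counts of 5 or fewer. Immunoglobulin segments and genes without an informative symbol were only counted.

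Shares of counts were compared with exact permutation tests over 25 comparisons, all p-values being two-sided. Fold changes of comparisons sharing libraries were set against 100 simulations of unchanged groups. Alternatives were DESeq2 1.42.0, limma-voom with library weights, RLE factors, library size alone, no low-count filter, a CPM filter of 1, no immunoglobulin genes, a fold minimum, all 18 libraries in a single fit, the replicate number as a block, and leaving out each library. Added after the data were seen were a fit without the 4 neonatal libraries whose median correlation with the other neonatal libraries was under 0.88 (WT replicate 1, HET replicates 1 and 2, KO replicate 4), a sex term read from Xist and Y-linked genes, tests of the adult-called genes as sets in the neonates, a test of Lin28b amounts against their score within genotypes, and a split of the adult WT libraries between comparisons.

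The steps were tested on simulated data in which some genes were changed by known folds. For the adult comparison (13510 genes), 4.48% of genes changed 1.5-fold, 37.1% of those changed 2-fold and 70.6% of those changed 4-fold were recovered, and 6 of 80 calls were false. For neonatal KO against WT (13741 genes) the shares were 1.45%, 5.56% and 40.8%, with 0 false among 33 calls. For neonatal WT against adult WT (13697 genes) they were 0%, 17.2% and 53.0%, with 1 false among 47. Camera recovered the raised list in each simulation and called none of the 21, 26 and 24 other lists, respectively. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists when genes are correlated.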

Results

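Gene expression was measured by RNA-seq in 18 libraries of immature B cells sorted from mouse bone marrow, in 5 groups. Adult mice with a tet-driven Lin28b transgene (n = 3) were compared with adult wild type (WT) mice (n = 3). Neonates 3 days old had no (KO), 1 (HET) or 2 (WT) functional Lin28b alleles (n = 4 each). Library totals, in M counts, were 27.8, 30.3 and 37.3 for the adult transgenic and 29.5, 27.4 and 37.2 for the adult WT libraries. They were 16.4, 27.0, 23.8 and 9.91 for the neonatal KO, 8.82, 6.38, 21.4 and 23.4 for the neonatal HET, and 12.8, 25.1, 21.99 and 21.2 for the neonatal WT libraries. The first 2 principal components held 23.4% and 13.7% of the variance. Means are followed by the standard deviation, and SE is the standard error of a log2 fold change.

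Lin28b (chromosome 10, 45376620 to 45486395 of GRCm38, minus strand) had 124, 62 and 109 counts in adult transgenic libraries 1 to 3 and 0, 0 and 0 in adult WT libraries. Counts were 43, 54, 100 and 173 in neonatal WT libraries 1 to 4, 0, 21, 82 and 77 in HET libraries, and 5, 0, 23 and 0 in KO libraries. Per M counts (CPM) these were 3.14 ± 1.22 in adult transgenic (n = 3), 4.56 ± 2.60 in neonatal WT, 2.61 ± 1.76 in HET and 0.318 ± 0.457 in KO libraries (n = 4 each). Against the floor of 3 counts over the 3 adult WT libraries, Lin28b was at least 96.8-fold higher in adult transgenic and at least 143-fold higher in neonatal WT libraries. In the neonates the edgeR log2 fold change was -3.76 (SE 1.52, adjusted p = 0.996) for KO against WT and -0.77 (SE 1.36, adjusted p = 1.00) for HET against WT, and neither passed. HET library 1, with 0 counts, and KO library 3, with 23, departed from the other libraries of their groups, so the genotypes of these 2 libraries are in doubt. In HET library 1, 30 genes with at least 10 CPM in every adult library also read 0. These genes numbered 77 in HET library 2, 114 in WT library 1 and at most 13 in the other neonatal libraries. The 0 for Lin28b there may thus not reflect the genotype, which was not tested. Both were kept under their labels, and leaving out either changed no count of calls between the neonatal groups or along alleles. A gene-level count does not show which part of a deleted gene is missing, and the transgene is written in the labels in human style (LIN28B), so its reads may be undercounted on the mouse genes.

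**Figure D1:**
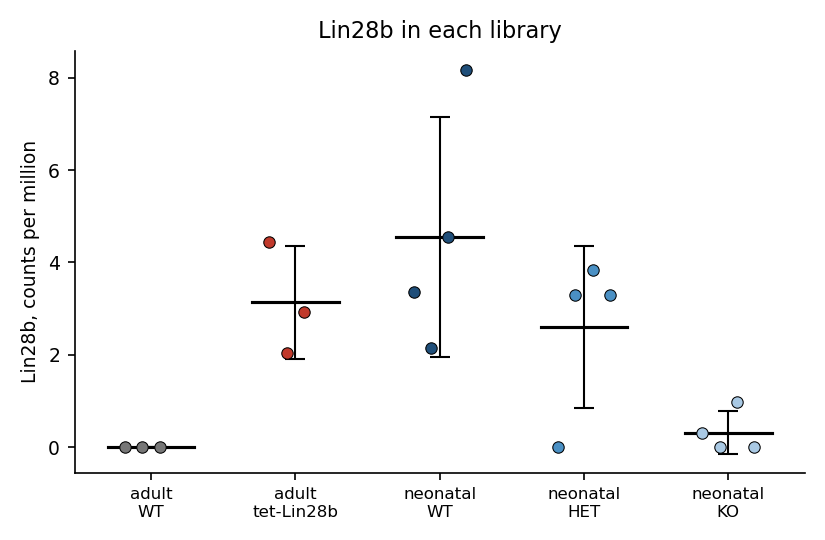
Lin28b in CPM in each of the 18 libraries, by group. Points at 0 had no counts.

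In adult transgenic cells, Igf2bp3, a fetal RNA-binding protein and let-7 target, rose from 9.07 ± 0.504 to 40.5 ± 11.7 CPM (log2 2.17, SE 0.24, n = 3 per group). Myc rose as well (log2 1.55, SE 0.23), and so did the scavenger receptor and fatty acid transporter Cd36, from 111 ± 5.28 to 293 ± 33.3 CPM (log2 1.41, SE 0.13). The lambda light chain constant gene Iglc2 fell from 1440 ± 202 to 432 ± 50.8 CPM (log2 -1.73, SE 0.14), and the microtubule-associated gene Map2 fell from 12.1 ± 3.81 to 0.249 ± 0.176 CPM (log2 -5.64, SE 0.57). Of 13884 genes tested with edgeR, 118 passed (38 higher and 80 lower), of which 22 and 66 changed at least 2-fold. In all 118 the 3 libraries of one group lay beyond the 3 of the other. That held for 23.1% of all tested genes, where chance gives 10%.

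Among genes with a mean of at least 5 CPM, the largest further rises were in Pacsin1 (log2 2.89, SE 0.31), the chemokine receptor Ccr6 (2.50, SE 0.33), the cytokine subunit Ebi3 (2.45, SE 0.22), Lst1 (1.98, SE 0.34), Gimap4 (1.58, SE 0.26) and the anti-apoptotic Bcl2a1d (1.57, SE 0.29). The largest further falls among them were in Bspry (-2.36, SE 0.44), the transcription factor Bhlha15 (-2.33, SE 0.28), Ndrg1 (-2.28, SE 0.29), Apbb1 (-2.25, SE 0.29), Nrxn1 (-2.20, SE 0.32), Prkar2b (-2.15, SE 0.32) and Trio (-2.15, SE 0.34). The receptor gene Slamf9 fell (-1.48, SE 0.14), and the Src-family kinase gene Hck fell from 1332 ± 103 to 631 ± 34.4 CPM (-1.07, SE 0.12). Of the early-life B cell genes, Cd5 (1.29, SE 0.39, adjusted p = 0.151 in edgeR), Arid3a (0.37, SE 0.27, adjusted p = 0.540) and Bhlhe41 (0.35, SE 0.19, adjusted p = 0.412) did not pass. Neither did Dntt (-1.20, SE 0.60, adjusted p = 0.362 in edgeR), which was lower in neonatal than in adult WT cells. Lin28a had 0 counts in all 18 libraries, and Igf2bp1, Igf2bp2 and Hmga2 were too low to be tested.

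By list, 4 of 36 tested let-7 targets rose and none fell, among them Igf2bp3, Myc and the chromatin protein gene Hmga1 (log2 0.87, SE 0.13), with 6 higher and 1 lower when adjusted over the list alone. The list was higher in camera (adjusted p = 0.00109, and adjusted p = 0.175 with an estimated correlation). Ribosome biogenesis had 3 of 40 members higher, Gar1 (1.00, SE 0.17), Gnl3 (0.87, SE 0.16) and Wdr12 (0.82, SE 0.14), 24 when adjusted over the list alone, and was higher as a list in camera (adjusted p = 2.85e-14, and adjusted p = 0.175 with an estimated correlation). For ribosomal proteins 87 of 89 log2 fold changes lay above 0 (median 0.49), with 0 passing and 38 higher when adjusted over the list alone (camera adjusted p = 7.35e-18, and adjusted p = 0.321 with an estimated correlation). For oxidative phosphorylation 75 of 77 lay above 0, with 0 passing and 44 higher when adjusted over the list alone (camera adjusted p = 2.11e-17, and adjusted p = 0.278 with an estimated correlation). Glycolysis had 1 of 19 members higher, Ldha (0.78, SE 0.12), and the list was higher in camera (adjusted p = 7.17e-04, and adjusted p = 0.278 with an estimated correlation).

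Translation factors were higher as a list in camera with 0 of 31 members passing and 2 higher when adjusted over the list alone (adjusted p = 2.23e-05, and adjusted p = 0.278 with an estimated correlation). The same held for S phase genes (0 of 26 passing, 6 higher when adjusted over the list alone, camera adjusted p = 3.28e-07, and adjusted p = 0.300 with an estimated correlation). G2/M genes had 25 of 26 values above 0 and none passing in either count (camera adjusted p = 2.39e-06, and adjusted p = 0.278 with an estimated correlation). Interferon response genes had 0 of 31 passing (camera adjusted p = 0.00970 higher, and adjusted p = 0.535 with an estimated correlation). Lambda light chain and editing genes had 2 of 10 lower, Iglc2 and Iglv3 (log2 -1.96, SE 0.20), 3 when adjusted over the list alone, and were lower in camera (adjusted p = 7.17e-04, and adjusted p = 0.278 with an estimated correlation). Of 221 tested immunoglobulin V, D and J segments, 7 fell and none rose.

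Pro-B and pre-B genes had 2 of 20 lower, Sox4 (log2 -0.84, SE 0.15) and the end-joining ligase gene Lig4 (-1.19, SE 0.21), and 2 higher and 4 lower when adjusted over the list alone. Mature B genes had 1 of 25 lower, the migration receptor gene Gpr183 (-1.37, SE 0.23), and 3 higher and 8 lower when adjusted over the list alone. Neither list passed in camera (adjusted p = 0.0970 each). BCR-induced early genes had 3 of 22 higher, Myc, Bcl2a1b (1.38, SE 0.19) and Bcl2a1d, and 4 when adjusted over the list alone (camera adjusted p = 0.366). B-1 cell genes had 1 of 19 higher, Plscr1 (1.14, SE 0.19), and 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.378). Apoptosis regulators had 2 of 18 higher in both counts, Bcl2a1b and Bcl2a1d (camera adjusted p = 0.117).

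BCR signalling components (0 of 29), imprinted growth genes (0 of 6), mitochondrially encoded genes (0 of 13) and cell stress genes (0 of 21) had no member passing. Their camera adjusted p were 0.0545, 0.0970, 0.908 and 0.840. When adjusted over the list alone, 2 BCR signalling components were lower, and 2 cell stress genes were higher and 1 lower. Of markers of other cells, 0 of 8 erythroid and 0 of 11 monocyte and macrophage genes passed (camera adjusted p = 0.0749 and 0.550), with 2 of the latter higher when adjusted over the list alone. Plasma cell markers had 1 of 10 higher, Mzb1 (log2 0.93, SE 0.12), and 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.117). Plasmacytoid dendritic markers had 1 of 8 higher, Pacsin1, and 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.493). Neutrophil (2), T and NK cell (4), megakaryocyte (1), stroma (3) and sex-linked (4) genes had under 5 tested members, and none passed.

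DESeq2 called 761 genes and limma-voom 627, all 118 edgeR calls being among those of DESeq2. The edgeR count was 61 without transgenic library 1, 20 without transgenic library 2, 169 without transgenic library 3, 20 without adult WT library 1, 17 without adult WT library 2 and 40 without adult WT library 3, and 21 with all 18 libraries in 1 fit. For the 30 named genes called here, 84 of 180 calls were kept over the fits leaving out 1 library. With all 18 libraries in 1 fit, 6 of the 30 were kept. Igf2bp3 did not pass without adult WT library 1 (adjusted p = 0.0590), and Myc did not without adult WT libraries 1 or 2 (highest adjusted p = 0.114 in edgeR).

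In neonates labelled Lin28b KO, Cd36 was lower, at 525 ± 50.5 CPM in WT and 247 ± 20.1 CPM in KO cells (log2 -1.04, SE 0.11, n = 4 per group, edgeR adjusted p = 0.00391), and HET cells held 403 ± 32.4 CPM. It was the only gene of 14213 to pass in KO against WT, with 677 at unadjusted p < 0.05, 35 calls by DESeq2 and 11 by limma-voom. Igf2bp3 was 87.3 ± 14.6 CPM in WT, 79.4 ± 29.7 in HET and 73.6 ± 6.19 in KO cells and did not pass (log2 -0.19, SE 0.25). The named genes with the next smallest p toward higher values, none passing, were the inhibitory coreceptor gene Cd72 (366 ± 27.7 CPM in WT and 685 ± 40.8 in KO, log2 0.96, SE 0.14, adjusted p = 0.0859 in edgeR), the interferon-induced Ifi27l2a (1.33, SE 0.20, adjusted p = 0.0859), Slamf9 (1.61, SE 0.27), Hck (0.84, SE 0.15) and Bhlhe40 (1.02, SE 0.19). Toward lower values these were Kpna2 (-1.24, SE 0.24), Rcc1 (-1.12, SE 0.25), Ppat (-0.96, SE 0.22) and Bzw2 (-0.68, SE 0.16). Iglc2 was 453 ± 166 CPM in WT, 795 ± 180 in HET and 1184 ± 253 in KO cells (log2 1.43, SE 0.27 for KO against WT, edgeR adjusted p = 0.246), and Map2 was 0.289 ± 0.337, 0.988 ± 1.15 and 7.79 ± 2.20 CPM. Myc (-0.34, SE 0.17), Arid3a (-0.52, SE 0.20), Cd5 (-1.95, SE 0.90) and Bhlhe41 (0.22, SE 0.34) did not pass. Dntt had 30 counts in KO, all in library 3, and 0 in WT and HET libraries.

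**Figure D2:**
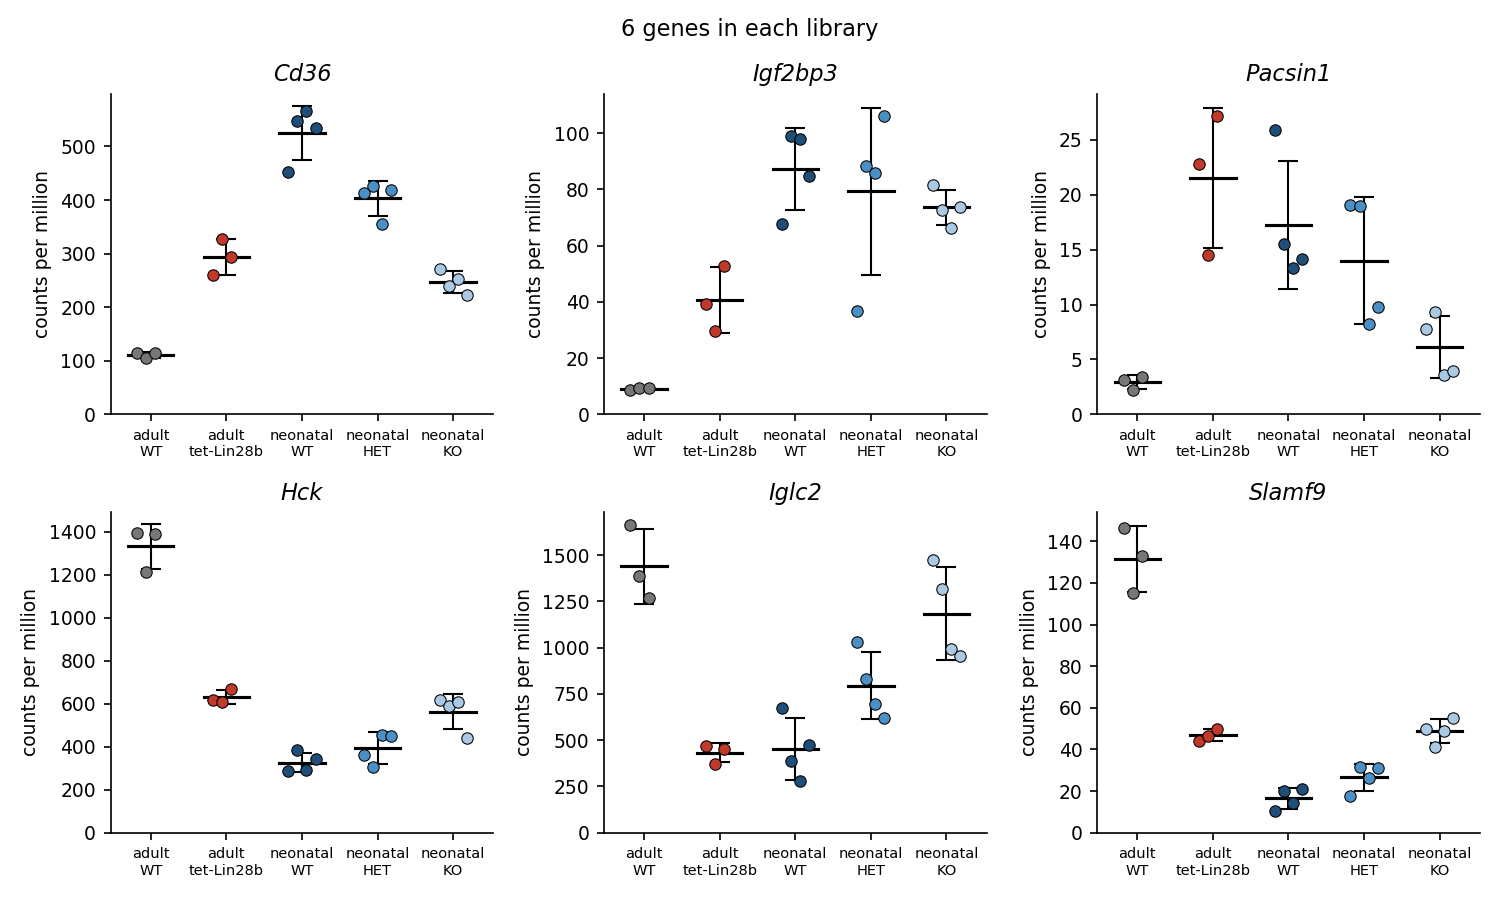
Cd36, Igf2bp3, Pacsin1, Hck, Iglc2 and Slamf9 in CPM in each library, by group.

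No member of any list passed in KO against WT, so lists are given by camera and by the count adjusted over the list alone. G2/M genes lay below 0 in all 26 (median log2 -1.33, adjusted p = 5.38e-10 in camera, and adjusted p = 0.302 with an estimated correlation). Ribosome biogenesis lay below 0 in all but 5 of 40, with 3 lower when adjusted over the list alone (camera adjusted p = 2.64e-09, and adjusted p = 0.0689 with an estimated correlation). Let-7 targets were lower as a list, with 10 of 39 above 0 (camera adjusted p = 0.00594, and adjusted p = 0.283 with an estimated correlation). Translation factors were lower (camera adjusted p = 0.00334, and adjusted p = 0.415 with an estimated correlation). Glycolysis was lower (camera adjusted p = 0.0164, and adjusted p = 0.302 with an estimated correlation), as were S phase genes (camera adjusted p = 0.00945, and adjusted p = 0.655 with an estimated correlation). Without the 4 low-correlation libraries translation factors and glycolysis did not pass in camera (adjusted p = 0.106 and 0.203).

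Interferon response genes lay above 0 in 26 of 28, with 1 higher when adjusted over the list alone (camera adjusted p = 9.35e-06, and adjusted p = 0.302 with an estimated correlation). All 9 lambda light chain and editing genes lay above 0, 4 of them higher when adjusted over the list alone (camera adjusted p = 9.35e-06, and adjusted p = 0.148 with an estimated correlation). Cell stress genes were higher, with 3 members when adjusted over the list alone (camera adjusted p = 5.56e-05, and adjusted p = 0.302 with an estimated correlation). Mature B genes were higher, with 22 of 25 above 0 (camera adjusted p = 1.04e-04, and adjusted p = 0.324 with an estimated correlation). BCR-induced early genes were higher (camera adjusted p = 0.00348, and adjusted p = 0.324 with an estimated correlation). BCR signalling components were higher, with 3 members when adjusted over the list alone (camera adjusted p = 0.0295, and adjusted p = 0.635 with an estimated correlation). Ribosomal proteins (adjusted p = 0.697), oxidative phosphorylation (0.163), erythroid (0.498), monocyte (0.993), stroma and endothelium markers (0.697) and mitochondrially encoded genes (0.697) did not pass in camera. The last 2 turned from lower to higher without the low-correlation libraries and passed there in camera (adjusted p = 0.00311 and 0.0217). Neonatal WT library 1, HET libraries 1 and 2 and KO library 4 correlated least with the other neonatal libraries (median r 0.853, 0.872, 0.856 and 0.865). Under RLE factors 2 genes passed in KO against WT, Cd72 higher and Cd36 lower.

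Between HET and WT neonates no gene passed in edgeR, with 303 at unadjusted p < 0.05, 1 call by DESeq2 (Ifi27l2a) and 3 by limma-voom (Ifi27l2a, Stat1 and Cd36). In each direction the 5 named genes with the smallest p were taken, namely Ifi27l2a (78.2 ± 12.7 CPM in WT and 184 ± 22.9 in HET, log2 1.28, SE 0.20, adjusted p = 0.369), Pim2 (0.79, SE 0.22), Stat1 (0.72, SE 0.18), Trim30a (0.72, SE 0.20), Neurl1a, Kpna2 (-0.86, SE 0.24), Naa15 (-0.79, SE 0.19), Tmem168 (-0.72, SE 0.21), Exosc9 (-0.64, SE 0.17) and Sept7 (-0.49, SE 0.14). Neurl1a had 0 counts in WT and 19 in HET libraries, at least 8.57-fold higher, or 4.43-fold without HET library 4. Interferon response genes lay above 0 in 27 of 28, 3 of them higher when adjusted over the list alone (camera adjusted p = 1.76e-07, and adjusted p = 0.400 with an estimated correlation). G2/M genes lay below 0 in all 26 (camera adjusted p = 9.31e-08, and adjusted p = 0.404 with an estimated correlation). Monocyte markers lay above 0 in 11 of 13 (camera adjusted p = 0.00615, and adjusted p = 0.404 with an estimated correlation), and all 8 erythroid markers lay above 0 without passing (camera adjusted p = 0.102). Ribosome biogenesis had 8 of 40 above 0 and was lower (camera adjusted p = 5.57e-04, and adjusted p = 0.400 with an estimated correlation). All 9 lambda light chain and editing genes lay above 0 (camera adjusted p = 4.40e-04, and adjusted p = 0.400 with an estimated correlation), and cell stress genes were higher (camera adjusted p = 5.24e-04, and adjusted p = 0.477 with an estimated correlation). Mature B genes (camera adjusted p = 0.00453, and adjusted p = 0.556 with an estimated correlation) and BCR-induced early genes (camera adjusted p = 0.00659, and adjusted p = 0.488 with an estimated correlation) were higher as lists. These 2 did not pass in camera without the low-correlation libraries (adjusted p = 0.252 and 0.0867) or with a sex term (adjusted p = 0.193 and 0.105). Calls gained in camera without those libraries were S phase genes lower and BCR signalling components and stroma markers higher (adjusted p = 4.87e-05, 0.0116 and 0.0352). Ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes turned from higher to lower and passed there in camera (adjusted p = 3.15e-05, 0.0195 and 0.0232). Haemoglobin was 0.0652 ± 0.119% of counts in HET and 0.00842% in WT libraries (exact two-sided p = 0.714), carried by HET library 2 with 0.243%, while the other 3 HET libraries held 0.00128 to 0.0136%.

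Between KO and HET neonates no gene passed in edgeR, with 427 at unadjusted p < 0.05, 3 calls by DESeq2 and 0 by limma-voom. DESeq2 called Cd36, Cd72 and Bhlhe40, and without HET library 4, 1 gene passed in edgeR, Cd72. Cd36 was lower in KO cells (log2 -0.70, SE 0.11) and Cd72 higher (0.95, SE 0.14), each with edgeR adjusted p = 0.133. The other named genes with the smallest p in each direction were Lgals3 (1.31, SE 0.34), Bhlhe40 (1.02, SE 0.19), Osbpl8 (0.68, SE 0.16), Cfp (0.55, SE 0.14), Tagap (-1.46, SE 0.42), Wdr36 (-0.67, SE 0.19), Prps2 (-0.60, SE 0.17) and Aqp1. The water channel gene Aqp1 reached 71.0 CPM in a HET library (mean 19.7 ± 34.4 CPM). All 8 erythroid markers lay below 0, 5 of them lower when adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.648 with an estimated correlation). Monocyte and macrophage markers were lower too, with 3 of 13 above 0 (camera adjusted p = 0.0239, and adjusted p = 0.551 with an estimated correlation). So were ribosome biogenesis (10 of 40 above 0, camera adjusted p = 0.0179, and adjusted p = 0.551 with an estimated correlation) and translation factors (6 of 31 above 0, camera adjusted p = 0.0153, and adjusted p = 0.648 with an estimated correlation). Glycolysis had 6 of 19 above 0 (camera adjusted p = 0.0239, and adjusted p = 0.551 with an estimated correlation). Without the low-correlation libraries, which include HET library 2 with most haemoglobin, none of these 5 lists passed in camera (adjusted p = 0.981, 0.0810, 0.161, 0.562 and 0.368 in the order given). The same fit gained calls in camera for mature B genes (adjusted p = 9.07e-08), lambda light chain genes (0.00492), cell stress genes (0.0138), BCR-induced early genes and BCR signalling components (0.0218 each), all higher. Calls gained toward lower values in camera were G2/M genes (adjusted p = 0.0138), S phase genes and let-7 targets (0.0218 each). Mitochondrially encoded genes and ribosomal proteins turned from lower to higher and passed there in camera (adjusted p = 1.27e-05 and 0.00492).

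Along the number of functional alleles, Cd36 rose by log2 0.52 per allele (SE 0.06, n = 12, edgeR adjusted p = 0.00754) and was the only gene to pass, with 731 at unadjusted p < 0.05, 40 calls by DESeq2 and 18 by limma-voom. It did not pass without KO library 2 (adjusted p = 0.0501). Slamf9 (-0.81, SE 0.13), Pdzd2 (-0.78, SE 0.15), Iglc2 (-0.71, SE 0.13), Cd72 (-0.48, SE 0.09), Hck (-0.42, SE 0.07), Gemin4 (0.73, SE 0.17), Kpna2 (0.62, SE 0.12), Rcc1 (0.56, SE 0.12) and Bzw2 (0.34, SE 0.08) did not pass. Ribosome biogenesis rose with alleles as a list, with 35 of 40 slopes above 0 and 3 higher when adjusted over the list alone, and it kept the call with an estimated correlation (camera adjusted p = 1.56e-09, and 0.0415 with an estimated correlation). G2/M genes had all 26 slopes above 0, none passing (camera adjusted p = 5.38e-10, and adjusted p = 0.282 with an estimated correlation). In KO against HET 11 of 26 lay above 0, and the list did not pass with all libraries (camera adjusted p = 0.187). The slope of this list thus lay mostly between WT and the other genotypes. Lambda light chain and editing genes had no slope of 9 above 0, 4 lower when adjusted over the list alone (camera adjusted p = 1.09e-05, and adjusted p = 0.114 with an estimated correlation). Let-7 targets had 29 of 39 slopes above 0 (camera adjusted p = 0.00552, and adjusted p = 0.186 with an estimated correlation).

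Interferon response genes were lower with more alleles, with 2 of 28 slopes above 0 and 1 lower when adjusted over the list alone (camera adjusted p = 2.72e-05, and adjusted p = 0.282 with an estimated correlation). In KO against HET 11 of 28 lay above 0 (median log2 -0.04) and the list did not pass (camera adjusted p = 0.696). Its median was 0.68 in HET against WT and 0.79 in KO against WT, so the slope lay mostly between WT and the other genotypes. Cell stress genes had 6 of 21 slopes above 0 and 3 lower when adjusted over the list alone (camera adjusted p = 3.29e-05, and adjusted p = 0.282 with an estimated correlation). Mature B genes had 3 of 25 slopes above 0 (camera adjusted p = 7.37e-05, and adjusted p = 0.282 with an estimated correlation). BCR-induced early genes (camera adjusted p = 0.00277, and adjusted p = 0.282 with an estimated correlation) and BCR signalling components (camera adjusted p = 0.0421, and adjusted p = 0.611 with an estimated correlation) were lower as lists. S phase genes were higher with more alleles (camera adjusted p = 0.00780, and adjusted p = 0.611 with an estimated correlation). Translation factors (camera adjusted p = 0.00277, and adjusted p = 0.408 with an estimated correlation) and glycolysis (camera adjusted p = 0.0201, and adjusted p = 0.282 with an estimated correlation) were higher as well. Without the low-correlation libraries those 2 did not pass in camera (adjusted p = 0.0792 and 0.180). Stroma markers and mitochondrially encoded genes turned from higher to lower with more alleles in that fit and passed there in camera (adjusted p = 0.00333 and 0.0327).

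Between neonatal and adult WT cells, ribosomal protein genes rose almost as a whole (84 of 90, 86 when adjusted over the list alone), among them Rps24 (log2 1.96, SE 0.16), Rps27a (1.88, SE 0.14) and Rpl3 (1.71, SE 0.15), with 4 neonatal and 3 adult libraries. Igf2bp3 rose from 9.07 ± 0.504 to 87.3 ± 14.6 CPM (3.26, SE 0.18), and Cd36 from 111 ± 5.28 to 525 ± 50.5 CPM (2.24, SE 0.10). Arid3a (2.11, SE 0.21), Cd5 (2.31, SE 0.49), Myc (1.36, SE 0.21) and Bhlhe41 (1.11, SE 0.23) rose as well. Cd72 fell from 2852 ± 217 to 366 ± 27.7 CPM (-2.96, SE 0.09), Hck fell (-2.03, SE 0.11), and the nonclassical MHC gene H2-Q7 fell from 328 ± 28.1 to 20.0 ± 8.73 CPM (-4.04, SE 0.32). In total 2031 of 14155 genes passed in edgeR (1135 higher and 896 lower), 739 and 353 of them by at least 2-fold. Libraries of the 2 groups did not overlap for 33.4% of tested genes, where chance gives 5.71%. Age coincided with strain, doxycycline food and marrow preparation.

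Genes with 0 counts in adult WT libraries were higher in neonatal WT cells at least 363-fold (Npr3), 282-fold (Hist1h4m), 269-fold (Col2a1), 231-fold (Col1a2), 157-fold (Col1a1) and 72.3-fold (the imprinted H19). Without neonatal WT library 1 the bounds were 127-fold for Col2a1, 94.1-fold for Col1a2 and 73.0-fold for Col1a1. Dntt, which encodes the nucleotide-adding enzyme TdT, was lower at least 51.7-fold, with 180 counts in adult WT and 0 in neonatal WT libraries (at least 32.4-fold without adult WT library 2). Other large changes were rises in Nid1 (6.04, SE 1.15), Fstl1 (5.26, SE 1.33), the asparagine synthetase gene Asns (5.09, SE 0.75) and Rap1gap2 (4.93, SE 0.46). Large falls were in Map2 (-5.34, SE 1.21), the interferon-inducible Tgtp2 (-5.08, SE 0.84), Il2ra (-4.43, SE 0.87), Neurl3 (-4.40, SE 0.87), Slc41a2 (-4.24, SE 1.01), Rapgefl1 (-4.03, SE 0.71) and Chd3 (-3.85, SE 0.95). Hba-a1 did not pass (3.11, SE 1.06).

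Ribosomal proteins were higher as a list between neonatal and adult WT cells (camera adjusted p = 6.29e-43, and adjusted p = 0.208 with an estimated correlation). Ribosome biogenesis had 18 of 40 higher, 27 adjusted over the list alone, with Npm1 at 1.72 (SE 0.14) and Ncl at 1.39 (SE 0.12). The list was higher in camera (adjusted p = 5.51e-11, and adjusted p = 0.122 with an estimated correlation). Translation factors had 17 of 31 higher, 18 adjusted over the list alone, with Eef1a1 at 2.10 (SE 0.14) (camera adjusted p = 1.84e-07, and adjusted p = 0.224 with an estimated correlation). G2/M genes had 22 of 26 higher, 24 adjusted over the list alone, with Cdk1 at 3.41 (SE 0.33) and Mki67 at 3.19 (SE 0.38). That list was higher in camera (adjusted p = 3.41e-13, and adjusted p = 0.214 with an estimated correlation). S phase genes had 8 of 26 higher, 10 adjusted over the list alone, with Tk1 at 1.89 (SE 0.30) (camera adjusted p = 4.40e-05, and adjusted p = 0.390 with an estimated correlation). Without neonatal WT library 1, 21 of the 26 S phase genes, 27 of 40 ribosome biogenesis genes and 18 of 38 let-7 targets were higher, and 26 of 30 interferon response genes, 14 of 25 mature B genes and 6 of 10 lambda light chain genes lower.

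Oxidative phosphorylation had 15 of 77 higher, 18 adjusted over the list alone, with Atp5g3 at 0.87 (SE 0.12) (camera adjusted p = 5.53e-07, and adjusted p = 0.390 with an estimated correlation). Mitochondrially encoded genes had 7 of 13 higher, 10 adjusted over the list alone, with mt-Co1 at 1.70 (SE 0.39) (camera adjusted p = 4.40e-05, and adjusted p = 0.361 with an estimated correlation). Glycolysis had 7 of 19 higher in both counts, adjusted over the list alone too, with Ldha at 1.05 (SE 0.11) (camera adjusted p = 0.0101, and adjusted p = 0.214 with an estimated correlation). Let-7 targets had 11 of 38 higher and 1 lower, Ccnd2, and 12 and 1 adjusted over the list alone (camera adjusted p = 1.39e-04, and adjusted p = 0.107 with an estimated correlation). B-1 cell genes had 8 of 20 higher and 2 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 0.00563, and adjusted p = 0.122 with an estimated correlation).

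Of interferon response genes 16 of 30 fell, 21 adjusted over the list alone, with Zbp1 at -2.06 (SE 0.30) and Stat1 at -1.27 (SE 0.15). The list was lower in camera (adjusted p = 5.19e-11, and adjusted p = 0.107 with an estimated correlation). BCR signalling components had 12 of 29 lower and none higher, among them Cd72 and Siglecg (-0.85, SE 0.08). They had 2 higher and 15 lower adjusted over the list alone (camera adjusted p = 0.00305, and adjusted p = 0.208 with an estimated correlation). Pro-B and pre-B genes had 2 of 21 higher and 6 lower, Sox4 at -1.94 (SE 0.13) and Ebf1 at -1.21 (SE 0.10). These were 2 and 7 adjusted over the list alone (camera adjusted p = 0.00650, and adjusted p = 0.122 with an estimated correlation). Mature B genes had 1 of 25 higher, Plac8 at 1.42 (SE 0.15), and 8 lower, Cd40 at -1.29 (SE 0.11). These were 4 and 10 adjusted over the list alone (camera adjusted p = 0.00650, and adjusted p = 0.299 with an estimated correlation). Lambda light chain and editing genes had 3 of 10 lower, Iglc2 at -1.65 (SE 0.28), Iglv3 at -1.70 (SE 0.42) and Igkc at -0.64 (SE 0.12). There were 3 adjusted over the list alone (camera adjusted p = 0.00305, and adjusted p = 0.208 with an estimated correlation). Of 215 tested immunoglobulin segments 21 fell and none rose. The immunoglobulin share of counts was 2.12 ± 0.17% in neonatal and 3.09 ± 0.23% in adult WT libraries (exact two-sided p = 0.0286, adjusted p = 0.357 over 25 permutation tests).

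Marker lists of other cells moved in several directions between neonatal and adult WT cells. Erythroid markers had 1 of 7 higher, Tfrc at 1.02 (SE 0.18), 4 adjusted over the list alone, in preparations without red cell lysis (camera adjusted p = 0.0456, and adjusted p = 0.377 with an estimated correlation). Without the low-correlation library (neonatal WT library 1) the camera adjusted p was 0.454, with 1 marker higher and 1 lower. Plasma cell markers had 1 of 10 higher, Mzb1 at 1.34 (SE 0.11), and 3 lower, Xbp1 at -1.16 (SE 0.09), 2 and 5 adjusted over the list alone (camera adjusted p = 0.0456, and adjusted p = 0.299 with an estimated correlation, or 0.0684 without neonatal WT library 1). Monocyte markers had 1 of 13 higher, Ly6c2 at 1.42 (SE 0.29), and T and NK cell markers 0 of 5 (camera adjusted p = 0.826 and 0.977). Plasmacytoid dendritic markers had 1 of 9 higher and 3 lower, Irf8 at -0.79 (SE 0.08) among them (camera adjusted p = 0.270). Stroma markers had 2 of 6 higher, Col1a1 and Col1a2 (camera adjusted p = 0.395). Imprinted genes had 2 of 7 higher, H19 and Igf2r at 1.83 (SE 0.33), and 1 lower, Gnas at -0.41 (SE 0.07) (camera adjusted p = 0.357). BCR-induced early genes had 4 of 23 higher and 2 lower (camera adjusted p = 0.292). Apoptosis regulators had 3 of 18 higher, Bcl2l11 at 1.75 (SE 0.24), and 2 lower (camera adjusted p = 0.977). Cell stress genes had 4 of 21 higher, Hsp90aa1 at 1.58 (SE 0.17), and 3 lower (camera adjusted p = 0.977).

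DESeq2 called 3270 genes and limma-voom 5033 between neonatal and adult WT cells. The edgeR count was 1024 without adult WT library 1, 1310 without adult WT library 2, 843 without adult WT library 3, 4361 without neonatal WT library 1 and 1283 without neonatal WT library 3.

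Between neonatal WT and adult transgenic cells, which both hold Lin28b (log2 0.52, SE 0.61, adjusted p = 0.639 in edgeR), 1528 of 14043 genes passed (828 higher and 700 lower in neonates, n = 4 and 3). Arid3a (1.72, SE 0.26) and Igf2bp3 (1.08, SE 0.23) were higher in neonates, and Cd72 (-2.34, SE 0.17) and H2-Q7 (-3.30, SE 0.32) lower. Myc (-0.20, SE 0.22), Cd5 (1.01, SE 0.36), Bhlhe41 (0.75, SE 0.20), Iglc2 (0.07, SE 0.29) and Pacsin1 (-0.33, SE 0.36) did not pass. Genes with 0 counts in adult transgenic libraries were higher at least 286-fold (Hist1h4m), 273-fold (Col2a1, or 129-fold without neonatal WT library 1) and 73.4-fold (H19), and Dntt was lower at least 23.5-fold. Further rises were in Fstl1 (4.98, SE 0.52), Nid1 (4.91, SE 1.22), Fosb (4.17, SE 0.97), Asns (4.09, SE 0.70), Flnb (3.67, SE 0.89), Sirpa (3.46, SE 0.74) and Hba-a1 (4.33, SE 1.08, with overlapping libraries). Further falls were in Tgtp2 (-5.26, SE 0.82), Ifit3 (-4.60, SE 0.91), Casp1 (-3.47, SE 0.70), H2-Q6 (-2.90, SE 0.39), Usp18 (-2.72, SE 0.46), Tsc22d1 (-2.69, SE 0.52) and Fcer2a (-2.63, SE 0.33).

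Interferon response genes were lower in neonatal WT than in adult transgenic cells (14 of 31, 24 adjusted over the list alone, camera adjusted p = 2.81e-11, and adjusted p = 0.373 with an estimated correlation). Of ribosomal proteins 66 of 89 were higher, 77 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.13e-27, and adjusted p = 0.491 with an estimated correlation). Of G2/M genes 15 of 26 were higher, 22 adjusted over the list alone, with Mki67 at 3.03 (SE 0.36) (camera adjusted p = 2.81e-11, and adjusted p = 0.491 with an estimated correlation). Of mitochondrially encoded genes 5 of 13 were higher, 9 adjusted over the list alone (camera adjusted p = 1.47e-04, and adjusted p = 0.498 with an estimated correlation). Erythroid markers lay above 0 in all 7, with 2 higher, Hba-a1 and Tfrc (1.33, SE 0.31), and 6 adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.498 with an estimated correlation). Translation factors had 10 of 31 higher and 1 lower, 10 and 5 adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.498 with an estimated correlation). Without neonatal WT library 1 these 2 lists did not pass in camera (adjusted p = 0.225 and 0.110). Pro-B and pre-B genes had 5 of 21 lower, 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0411, and adjusted p = 0.373 with an estimated correlation). B-1 cell genes had 3 of 20 higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0439, and adjusted p = 0.373 with an estimated correlation).

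Ribosome biogenesis (7 of 40 higher and 2 lower) and oxidative phosphorylation (1 of 77 higher and 3 lower) did not pass as lists in camera (adjusted p = 0.0657 and 0.248). Neither did let-7 targets (6 of 38 higher, Insr at 2.39, SE 0.24, and 2 lower) or lambda light chain genes (1 of 9 lower) in camera (adjusted p = 0.205 and 0.208). Without neonatal WT library 1, oxidative phosphorylation (2 of 77 higher and 13 lower) and lambda light chain genes (2 of 9 lower) passed as lower in camera (adjusted p = 0.0301 and 0.0321). In that fit mature B genes and BCR signalling components were lower and S phase genes higher in camera (adjusted p = 0.0254, 0.0403 and 4.76e-04), which did not pass with that library (adjusted p = 0.156, 0.156 and 0.0585). Of 215 immunoglobulin segments 26 fell and none rose. DESeq2 called 3009 genes and limma-voom 4704. The edgeR count was 832 without transgenic library 1, 446 without transgenic library 2, 594 without transgenic library 3, 3577 without neonatal WT library 1, 783 without neonatal WT library 2, 627 without neonatal WT library 3 and 740 without neonatal WT library 4.

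The gain in adults and the age difference shared 27 higher genes (3.08 by chance if independent) and 47 lower genes (5.29 by chance), with 1 gene, Slfn2, in opposite directions. Shared genes included Igf2bp3, Cd36, Pacsin1, Myc, Mzb1 and Ldha among the higher and Map2, Iglc2, Iglv3, Hck, Slamf9 and Sox4 among the lower. Log2 fold changes across 13550 genes, which are not independent, had r = 0.380. In 100 simulations of unchanged groups sharing the same adult WT libraries, r was 0.422 on average (0.390 to 0.451) with 0 shared calls. Unchanged groups have few or no calls, so that 0 does not show how many shared calls the shared libraries would add. The covariance was 0.243 against 0.0927 in those simulations. With the 3 adult WT libraries split 2 and 1 between the comparisons, a test chosen after the results were seen, r was 0.182 on average over 6 splits (0.126 to 0.240). No call was shared in any split. In each split 1 of the comparisons had at most 1 call, so the splits cannot test the shared calls.

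**Figure D3:**
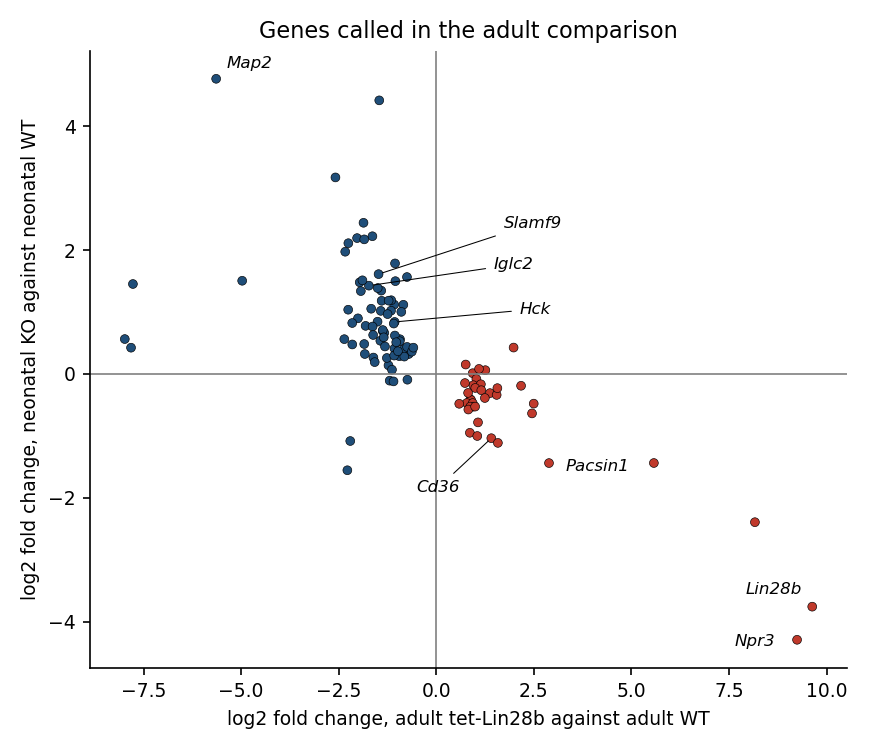
Log2 fold changes of genes called in adult transgenic against adult WT cells, set against those of neonatal KO against neonatal WT cells. Genes at 0 in 1 adult group, Lin28b and Npr3 among them, are placed by the prior count.

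The gain in adults and the loss in neonates shared no library, and their log2 fold changes had r = -0.225 across 13302 genes and -0.303 for genes with a mean CPM of at least 5. Cd36 was the only gene called in both, higher with the transgene and lower in KO cells (0.00286 genes by chance). For KO against WT and neonatal against adult WT, which share neonatal WT libraries, r was -0.405 (13747 genes), and in simulations of unchanged groups it was -0.533 on average (-0.563 to -0.500). With the neonatal WT libraries split 2 and 2, r was -0.0885. For KO against HET and neonatal against adult WT, which share no library, r was -0.124. A test of whether the adult gain differed from the neonatal loss called 0 of 15504 genes in edgeR, with 463 at unadjusted p < 0.05, 11 calls by DESeq2 and 0 by limma-voom. Igf2bp3 (log2 difference 1.96, SE 0.37, adjusted p = 0.450), Ifi27l2a (1.74, SE 0.32, adjusted p = 0.450), Lst1 (2.39, SE 0.59), Myc (1.19, SE 0.29), Pkig (0.74, SE 0.16), Kdm5b (-1.25, SE 0.35), Neat1 (-1.10, SE 0.27) and Mbnl1 (-0.59, SE 0.16) had the smallest p in their direction, besides Reep1 and Dock4, which had a mean under 3 CPM in every group.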

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

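Tests of the 4 low-correlation libraries, the sex term, the number of functional Lin28b alleles, the amount of Lin28b within genotypes, the genes with ribosomal RNA-like reads and the genotypes of the low-correlation libraries were chosen only after the results were seen. In each neonatal group of 4 libraries, 23 measures were screened for a library far from the other 3, which gave 62 groups with any spread. For measures with a continuous spread, chance alone would single out about 1 in 20 groups, or 3.1, and 11 were found. That rate does not hold where the other 3 libraries stood at 0, since any count was then flagged. This was so for Igf2bp2 in WT library 4 and KO library 3 and for Dntt in KO library 3. Several measures also overlap, so 11 against 3.1 does not show an excess.

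Mitochondrial genes made up 3.18% of counts (95% Wilson interval 3.17 to 3.19) in neonatal WT library 1 and 1.14 to 1.29% in the other 3. HET libraries 1 and 2 held more (4.13% and 3.69%, against 1.17% and 1.27% in HET libraries 3 and 4). They were not flagged, since the screen looks for 1 library apart from the other 3. Haemoglobin made up 0.243% (0.239 to 0.247) in HET library 2 and 0.00128 to 0.0136% in the other 3. The 10 genes with most counts held 8.17% (8.15 to 8.18) in WT library 1 (5.88 to 6.27% in the others) and 14.5% (14.505 to 14.549) in KO library 4 (6.09 to 7.46% in the others). Lin28b stood at 0 CPM in HET library 1 and at 3.29 to 3.84 CPM in the other HET libraries, and the floor of 3 counts in that library was 0.340 CPM. Igf2bp2 was 0.142 CPM in WT library 4 and 0 in the others, 1.70 CPM in HET library 1 and 0 to 0.234 in the others, and 0.0842 CPM in KO library 3 and 0 in the others. Hmga2 was 0.504 CPM in KO library 4 and 0 to 0.0371 in the others. Dntt was 1.26 CPM in KO library 3 and 0 in the others.

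Lars2 took 3.84% of counts (95% Wilson interval 3.83 to 3.85) in KO library 4 and 0.143 to 0.210% in the other KO libraries. Gm42418, Gm26917, CT010467.1 and mt-Rnr2, which hold or share ribosomal RNA sequence, were 3.89-fold, 7.87-fold, 5.94-fold and 3.84-fold above the median of the other 11 neonatal libraries there, and Lars2 was 25.3-fold above it. For mt-Rnr2 another neonatal library reached 10093 CPM against 12695 CPM in KO library 4. A candidate explanation is therefore more ribosomal RNA in this library, since the smallest of the 4 folds was 3.84. No biological explanation was tested.

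Neonatal WT library 1, HET library 2, KO library 4 and HET library 1 had median correlations of 0.853, 0.856, 0.865 and 0.872 with the other neonatal libraries, the lowest of the 12. After thinning all 12 to 6.38 M counts the lowest 4 were still these 4, which argues against the number of counts alone. These 4 also had the lowest totals (12.8, 6.38, 9.91 and 8.82 M counts in the order given), against 16.4 M or more in the others. Thinning cannot test whether what lowered their totals also lowered their correlations. The 4 libraries came from 3 genotypes, which argues against the genotype of Lin28b. Differences in RNA quality between preparations may remain, and they were not tested beyond these 4 libraries.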

How the results depend on the processing

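The fits without the low-correlation libraries and with a sex term, and the split of adult WT libraries, were chosen only after the data were seen, and the other alternatives before. No named gene that passed turned its direction under any alternative. Of 118 adult calls 117 were called by limma-voom, 74 were kept with the replicate number as a block and 20 with all 18 libraries in 1 fit. The sex term, library size alone, the CPM filter and leaving out immunoglobulin genes left each count of calls within 1.5 times, and leaving immunoglobulin genes out changed none of the 15 shares by more than the spread between replicates. With an estimated correlation 71 list calls were lost. Of the calls of the fixed lists, only that of ribosome biogenesis in the allele trend was kept. The other list results thus rest on the preset correlation. Without the low-correlation libraries 14 list calls were lost, 16 were gained, and 27 lists turned direction without being called both ways, some of them passing in that fit only. Over fits leaving out 1 library, 80 list calls were lost, 72 were gained, and in 109 cases a list turned direction without being called both ways. Where a count moved, the cause was not tested, except that a fold minimum can only remove calls. At these depths, folds of 2 were recovered in 5.56% of simulated cases for the neonatal and 37.1% for the adult comparison.

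Counts of calls in the adult comparison (118) were 761 with DESeq2, 352 with no filter, 627 with limma-voom and 21 with all 18 libraries, and 17 to 169 leaving out 1 library. For KO against WT (1) they were 35 with DESeq2, 2 with RLE factors, 3 with no filter, 11 with limma-voom and 8 with all 18 libraries (Cd72 was added with RLE factors, and Cd72 and Ifi27l2a with no filter), and 1 to 1 leaving out 1 library. For HET against WT (0) they were 1 with DESeq2, 1 with no filter and 3 with limma-voom, and 0 to 0 leaving out 1 library. For KO against HET (0) they were 3 with DESeq2 and 3 with all 18 libraries, and 0 to 1 leaving out 1 library. For the allele trend (1) they were 0 with a fold minimum, 40 with DESeq2, 18 with limma-voom, 5 with all 18 libraries and 4 without the low-correlation libraries (Cd36, Hck, Iglc2 and Myo1e), and 0 to 1 leaving out 1 library. For neonatal against adult WT (2031) they were 1092 with a fold minimum, 3270 with DESeq2, 5033 with limma-voom and 4361 without the low-correlation libraries, and 843 to 4361 leaving out 1 library. For neonatal WT against adult transgenic (1528) they were 873 with a fold minimum, 3009 with DESeq2, 4704 with limma-voom and 3577 without the low-correlation libraries, and 446 to 3577 leaving out 1 library. For the difference of gain and loss (0) they were 11 with DESeq2, and 0 to 0 leaving out 1 library. The correlation of KO against HET with the age difference was -0.202 for genes with a mean CPM of at least 5 (-0.124 for all), and that of KO against WT was -0.0885 with the WT libraries split 2 and 2 (-0.405 otherwise). That of the adult gain with the age difference was 0.182 with the adult WT libraries split 2 and 1 (0.380 otherwise).

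With the replicate number as a block (replicate block), counts were 84 in the adult comparison, 2 in KO against WT and 2 in the trend (Cd36 and Iglc2 in both), 676 in neonatal against adult WT and 0 in neonatal WT against adult transgenic cells. The last 2 fits also left out neonatal WT library 4, which has no adult partner number, and without it and with no block the counts were 1452 and 740. Libraries sharing a number did not consistently deviate together: correlations were -0.0400 to 0.130 for the adult groups, -0.0539 to 0.193 for KO and WT, -0.0376 to 0.241 for HET and WT, -0.0352 to 0.274 for KO and HET and -0.0156 to 0.0167 for neonatal and adult WT. Some neonatal libraries of different numbers and genotypes did deviate together, such as KO library 3 and HET library 4 (0.308). Others deviated in opposite ways, such as HET library 4 and WT library 1 (-0.239). The reason was not tested. Libraries correlated best with their own number in 1 of 3, 1 of 4, 2 of 4, 2 of 4 and 0 of 4 cases, which shows no consistent pairing. With 3 or 4 libraries per group this cannot exclude that the numbers pair some samples.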

Other observations

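The tests of the adult-called genes in neonates, and those of the low-correlation libraries, the sex term, the slope per allele, that slope without HET library 1 and KO library 3, and the amount of Lin28b within genotypes, were chosen only after the results were seen, unlike the counts over other splits. For the cycling test and the split test of the score, the outcomes to look for were set beforehand. The score itself rests on the adult-called genes, whose tests in neonates were chosen afterwards.

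Genes called in adult transgenic cells lay on the opposite side of 0 in neonatal KO cells. Of 38 genes higher in adults, 33 were below 0 in KO against WT (median log2 -0.44, all genes 0.03, camera p = 9.61e-13 and p = 4.26e-04 with an estimated correlation, adjusted over 14 set tests 0.00298). Of 77 tested genes lower in adults, 72 were above 0 (median 0.77, camera p = 2.21e-17 and p = 0.00207 with an estimated correlation, adjusted 0.00921). In KO against HET 32 of 38 were below 0 (adjusted p = 1.02e-07 in camera, and 0.00921 with an estimated correlation) and 64 of 77 above (adjusted p = 6.22e-09 in camera, and 0.0301 with an estimated correlation). In HET against WT 29 of 38 and 57 of 77 did so, and both sets passed in camera (adjusted p = 0.00983 and 3.27e-04, and adjusted p = 0.115 and 0.126 with an estimated correlation). Without the low-correlation libraries the camera p of these 2 sets were 5.26e-08 and 1.22e-10. At unadjusted p < 0.05 in KO against WT, 38 of 115 adult-called genes were opposite (4.45 by chance), with Cd36, Slamf9, Hck and Iglc2 at the smallest p, and 0 were in the same direction (1.2 by chance). Genes are not independent, which these counts ignore.

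A score per neonatal library, the mean log2 CPM of the adult-higher genes minus that of the adult-lower genes, was 2.34 ± 0.48 in WT, 1.80 ± 0.60 in HET and 0.66 ± 0.31 in KO libraries (n = 4 each). It was -1.68 for KO minus WT and -1.14 for KO minus HET (exact two-sided p = 0.0286 each, the smallest that 4 against 4 can give, adjusted p = 0.0381 by permutation) and -0.54 for HET minus WT (exact two-sided p = 0.200).

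A candidate explanation is the number of functional Lin28b alleles, as the score rose by 0.84 per allele (exact p = 0.00104 over 34650 arrangements, two-sided, 0.00185 without Lin28b in the score) and, without Lin28b and without HET library 1 and KO library 3, whose genotypes are in doubt, by 0.72 (exact p = 0.00667 over 4200 arrangements). Within genotypes Lin28b and the score without Lin28b ran opposite without passing (r = -0.545, exact two-sided p = 0.153). HET library 1 (0 CPM) scored 2.30 and HET libraries 2 to 4 (3.29 to 3.84 CPM) 1.32 to 2.61. KO library 3 and WT library 4, with most Lin28b in their groups, scored lowest there (0.394 and 1.88). The test did not pass and includes the libraries of doubted genotype. It therefore cannot decide whether the amount of Lin28b per library plays a part. The low-correlation libraries and the sex make-up of the groups are argued against as the whole cause, since both sets kept their direction without those libraries (larger camera p = 2.74e-09) and with a sex term (larger camera p = 4.75e-14). KO libraries 1 and 2, HET libraries 1, 2 and 4 and WT library 4 read as female. These camera p use the preset correlation only. With all libraries, an estimated correlation raised the p of these sets to 4.26e-04 and 0.00207. For a difference in cycling cells, 122% of the KO minus WT difference was left with the cycling mean as a term (-2.05, SE 0.34, against -1.68, SE 0.34). That term assumes 1 slope for all 12 libraries. The score fell with cycling over the KO libraries (0.96 at 3.83 to 0.26 at 5.27). Over WT libraries 2 to 4 it rose (1.81 at 5.45 to 2.33 at 6.24), while WT library 1 scored 2.98 at 4.51. The adjustment therefore does not exclude cycling. Effects of litter or preparation day, which the labels do not give, stay open and untested. Some neonatal libraries of different genotypes did deviate together across genes (r = 0.308 for KO library 3 and HET library 4).

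Other splits of the libraries were compared with the real groups. For the score, only the real 1 of 35 splits of the 8 KO and WT libraries gave a difference of 1.68, the highest other being 1.26, which argues against chance. In the adult comparison 10 splits are too few, with 118 calls in the real split and 0 in the highest other (1 of 10 as large). The splits argue against chance for KO against WT (1 call, highest other 0, 1 of 35 splits as large), neonatal against adult WT (2031 calls, highest other 38, 1 of 35), neonatal WT against adult transgenic (1528 calls, highest other 0, 1 of 35) and the trend (1 call, highest other 1, 2 of 100). The splits say nothing on chance for HET against WT (0 calls in edgeR, highest other 0, 35 of 35), KO against HET (0 calls, highest other 1, 35 of 35) and the difference of gain and loss (0 calls, highest other 4, 100 of 100), since every split has at least 0 calls. Their edgeR counts at unadjusted p < 0.05 were 303, 427 and 463, with 1, 3 and 11 calls by DESeq2 and 3, 0 and 0 by limma-voom.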
